A study of Caenorhabditis elegans with 2 samples.

How the data were processed

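The 2 samples were biological replicates of 1 group: sonicated chromatin (fragments of 200 to 800 bp per the labels) from whole mid-stage embryos of a strain with TY1, EGFP and 3xFLAG tags at ztf-23, precipitated with an anti-GFP antibody. One label names ztf-23 as the antibody and the description names GFP; the tag is what the GFP antibody recognises. The labels name a control experiment, which was not analysed here.

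Values started from the authors' peak lists on build ce11, per the labels. There were 8 lists: for each replicate alone and for both replicates combined, a ranked list of all regions and a shorter thresholded list, with 2 versions of each combined list. Thresholding was by IDR, the irreproducible discovery rate, which compares ranks between replicates or between pseudo-replicates. Per the deposited file descriptions, each thresholded list was made with 1 further input file that the ranked lists lack. The aligner, the peak caller, their settings and the read depth were not given in the sources used here, so no depth per sample can be stated. The signal value is the peak caller's own, as deposited by the authors; its scale is not stated, and it was used to rank and describe peaks, not to compare lists. The score from 0 to 1000, deposited by the authors, rises with reproducibility between replicates and starts at 830 in the conservative list. The ranked lists also hold a −log10 IDR per region, deposited by the authors, which was read and not used in any result. Single-replicate signals of a conservative peak were taken from the strongest overlapping region of that replicate's ranked list.

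The reference was WBcel235, the same assembly as ce11, with gene annotation release 115; every region of every list ended within its chromosome's length. Gene-based measures used nuclear chromosomes, with 19973 protein-coding genes. Coordinates are printed 1-based.

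Chance for positions came from circular shifts of all summits by a random offset per chromosome, 10000 times for the share near starts, the divergent pairs and the replicate overlap, and 1000 times for the 7 genomic classes and the 9 non-coding classes. A promoter was the 500 bp upstream of a gene start, and a summit took the first class that applied among promoter, 5' UTR, coding exon, 3' UTR, non-coding exon, intron and intergenic. Upstream against downstream, X against autosomes and centres against arms used exact binomial tests, which treat peaks as independent although neighbouring peaks are not. Gene lists were tested with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 31 lists and a threshold of 0.05. Words of 8 bases were compared between a window reaching 50 bp to either side of each summit and 2 flanking windows of the same width, with discovery on I, II and III and the test on IV, V and X. Intervals of shares are exact Clopper-Pearson intervals at 95% and cover counting error only.

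The lists, fixed at the start, were ribosomal proteins, histones, proteasome subunits, respiratory chain and ATP synthase, heat shock and chaperones, Hox genes, endoderm and intestine regulators, pharynx, body wall muscle, epidermis, neuronal fate regulators, pan-neuronal genes, germline and P granule genes, cell cycle and DNA replication, Wnt and Notch pathways, dosage compensation and condensin, chromatin regulators, ztf zinc finger genes, nuclear hormone receptors, ceh homeobox genes, bHLH genes, collagens, chemoreceptors, major sperm proteins, splicing factors, translation factors, aminoacyl-tRNA synthetases, small RNA pathway, vacuolar ATPase, and tubulins and actins. The named genes followed a rule fixed with them: the 25 strongest conservative peaks that overlap a peak of both own lists, each named by the nearest gene start within 1000 bp; the 4 strongest bound members of each list past the threshold and the strongest of every other list; the 4 strongest genes of each non-coding class past the threshold; and ztf-23. It was applied to nuclear peaks, and mitochondrial peaks are described separately. The closest protein-coding gene is added where another gene is nearer. Names outside the rule (set-16, ctf-4 and the RNA genes and loci in the closing section) were chosen after their values were seen.

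The alternatives fixed before the data were examined were the other combined list, a score of at least 830, the 500 strongest peaks, each replicate's own list in place of the combined one, other windows, starts, denominators, assignments, word lengths and backgrounds, and other overlap rules. Peak sets without overlapping or small-RNA peaks, protein-coding denominators, the nearest protein-coding start and leaving out chromosome IV were added after seeing the data.

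The tests were checked on simulated data. Random summits in place of the 2213 nuclear ones were called near gene starts in 6% of 100 runs. With random bound genes among 19973, no list was called in 100 runs. The proteasome list (33 members) with 25% of its members added was called in 87% of runs. Other lists, some with fewer members, were not tried in this way. Random summits gave no called genomic or non-coding class in 20 runs. These runs used fewer shifts than the main tests, too few for a single class to pass after adjustment. They therefore do not give the rate of false calls of single classes. In shuffled windows no word was called, and a word placed in 5% of windows ranked 1 among 12566. The shuffled centre and flank windows were drawn from 1 pool, so their base composition could not differ. This check therefore does not cover words that differ through base composition. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Signal tracks and reads were not used here.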

Results

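Chromatin immunoprecipitation and sequencing (ChIP-seq) was used to locate a GFP-tagged zinc finger protein on DNA in *Caenorhabditis elegans* embryos. The worms carried a CRISPR insertion that fused TY1, EGFP and 3xFLAG tags to the product of ztf-23 on chromosome I, and whole mid-stage embryos obtained by egg bleaching (age 1.5 hours per the labels) were precipitated with an anti-GFP antibody. The series held 1 group of 2 biological replicates, so there was no comparison between groups, and no control library was analysed here. Read depth per replicate was not given in the sources used here, so the values below rest on the authors' peak lists on genome build ce11. The combined list named conservative by the authors, used for all main values, held 2234 peaks, of which 2213 lay on the nuclear chromosomes and 21 on the mitochondrial chromosome. Its peaks had a median width of 344 bp. The other combined list held 2413 peaks, 1.08 times as many. The conservative list was not a subset of it: 1933 of the 2234 conservative peaks overlapped a peak of the other list. Both lists had a lowest score of 830.

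The strongest peaks stood far above the rest, and several lay upstream of genes for translation factors and other proteins of protein synthesis. A group of 9 nuclear peaks, set apart after the values were seen, had signal values from 3088 to 19378, while the highest of the remaining nuclear peaks had 1825 and the median nuclear peak had 128. The closest protein-coding genes to these 9 were trap-3, which encodes a translocon-associated protein of the endoplasmic reticulum, eef-1G, eef-1A.2 and drr-2, which encode translation factors, icd-1, a subunit of the nascent polypeptide-associated complex, rpl-24.1, a ribosomal protein, dkc-1, the pseudouridine synthase of small nucleolar ribonucleoproteins, wip-1 and tasp-1. No test for a shared function was run on these 9, and 5 of their summits were nearer to the start of a non-coding gene. The drr-2 summit also lay upstream of the divergent gene set-16, so that peak cannot be given to drr-2 alone. All 9 summits were in the 500 bp upstream of an annotated gene start. Signal fell to 452 at rank 100 and 200 at rank 500.

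In detail, the top peak (IV: 2388847 to 2389436, signal 19378) had its summit 47 bp upstream of the start of the non-coding gene Y38F2AR.16 and 301 bp upstream of trap-3. The peak at eef-1G (V: 10965423 to 10965966, signal 17955) had its summit 27 bp upstream of the gene start. At drr-2 (III: 13643474 to 13644012, signal 17132) the summit was 170 bp upstream. Next came the peak at the non-coding gene C56C10.15, 374 bp upstream of icd-1 (II: 6588733 to 6589399, signal 14986), and that at the annotated piRNA gene 21ur-11631, 255 bp upstream of rpl-24.1 (I: 4584558 to 4585118, signal 14280). The wip-1 peak (III: 5018032 to 5018546, signal 13971) was 331 bp upstream of the start. The peaks at K01G5.11, 228 bp upstream of dkc-1 (III: 10747936 to 10748444), and at R03G5.8, 312 bp upstream of eef-1A.2 (X: 7823127 to 7823566), had signals of 7410 and 4569. At tasp-1 (III: 10759039 to 10759433, signal 3088) the summit was 62 bp upstream.

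**Figure D1:**
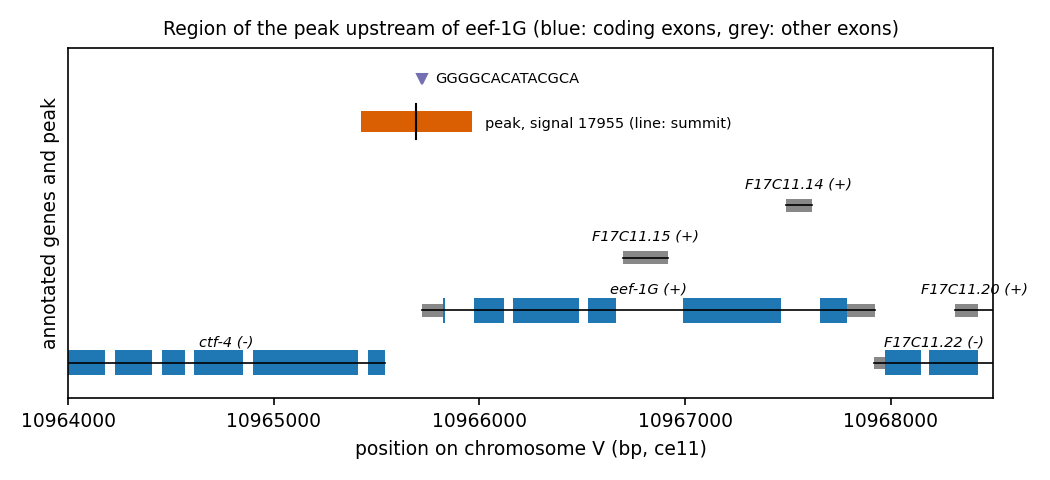
Map of chromosome V around the peak upstream of eef-1G, with position in bp (ce11) on the horizontal axis, coding exons in blue, other exons in grey, the peak in orange and its summit as a line. The peak of signal 17955 covers the starts of eef-1G and of the divergent gene ctf-4, and the triangle marks the sequence GGGGCACATACGCA at 10965712.

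Most named strong peaks, 15 of 25, were nearest to a non-coding gene start, and 15 of 25 had a protein-coding start within 1000 bp. Of the 25 strongest nuclear peaks that overlapped a peak in both replicates' own lists, 8 had a protein-coding start as the nearest start, 6 a snoRNA gene, 6 another ncRNA gene, 2 a tRNA gene and 1 a piRNA gene, and 2 had no gene start within 1000 bp. The snoRNA genes, whose products guide modification of other RNAs, were C51F7.4 (signal 1465), W03C9.9 (1273), T06C12.16 (1204), ZK265.10 (1091), T03F7.8 (1077) and ZK994.7 (1062). The tRNA genes were C04A11.t1 (signal 874) and W03G11.t1 (833), both on X. The other named starts were those of hsd-2 (signal 1581), K12H4.5 (1468), ent-2 (1020), rpl-3 (900), ZC53.9 (1825) and C04G6.15 (879). The peaks without a start within 1000 bp were on III at 8412008 to 8412290 (signal 941), in intergenic DNA, and on V at 2185555 to 2185800 (signal 821), in an intron of cyp-33C2.

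The replicates shared most of their peaks. Replicate 1 had 959 peaks in its own list and replicate 2 had 1233, 1.29 times as many. Of the replicate 1 peaks, 738 (77.0%) overlapped a replicate 2 peak by at least 1 bp, against 2.42% when replicate 2 peaks were shifted along the chromosomes (one-sided permutation p = 0.0001, the smallest that 10000 shifts can give). From the other side, 736 of the 1233 replicate 2 peaks (59.7%) overlapped a replicate 1 peak. Spearman's rho of the signal across the 738 shared peaks was 0.793 (95% interval 0.765 to 0.818); it is across peaks, which are not independent replicates.

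The named strong peaks were chosen for presence in both replicates. The eef-1G peak had signal 8496 in replicate 1 and 9477 in replicate 2, the trap-3 peak 9129 and 10262, the tasp-1 peak 1363 and 1710, and the snoRNA gene C51F7.4 666 and 810. Over the 2210 conservative peaks found in both ranked lists, the ratio of replicate 2 to replicate 1 signal had a median of 1.18, with 5th and 95th percentiles of 0.783 and 1.78; the lists were scored separately, so the ratio carries any difference in depth. Across those 2210 peaks rho was 0.670. Of the conservative peaks, 700 overlapped a peak in both own lists and 1038 overlapped a peak in neither.

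**Figure D2:**
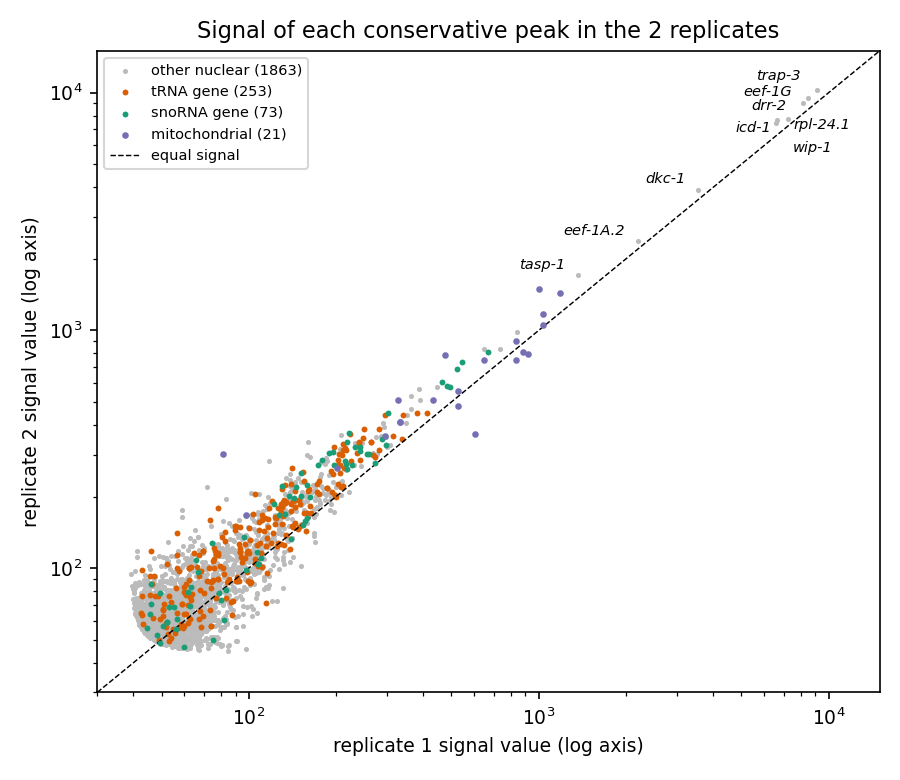
Signal value of each conservative peak in replicate 1 (horizontal, log axis) and replicate 2 (vertical, log axis), coloured by whether the summit lies within 200 bp of a tRNA or snoRNA gene or on the mitochondrial chromosome; the dashed line marks equal signal. The 9 strongest nuclear peaks, labelled by their closest protein-coding gene, run from tasp-1 (1363 and 1710) to trap-3 (9129 and 10262).

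Peaks gathered at gene starts. Of the 2213 nuclear summits, 1382 (62.4%, exact 95% interval 60.4 to 64.5%) lay within 500 bp of an annotated gene start, against 29.0% ± 1.07 (SD over shifts) in 10000 circular shifts (one-sided permutation p = 0.0001, the smallest possible). With starts of protein-coding genes alone the share was 39.7% against 18.5%. Around all starts the median summit was 45 bp upstream, with 857 summits upstream and 521 downstream (62.2% upstream, exact binomial p = 1.2e-19, two-sided). Around protein-coding starts it was 160.5 bp upstream, and 735 of 878 summits (83.7%) were upstream (exact binomial p = 1.3e-96).

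**Figure D3:**
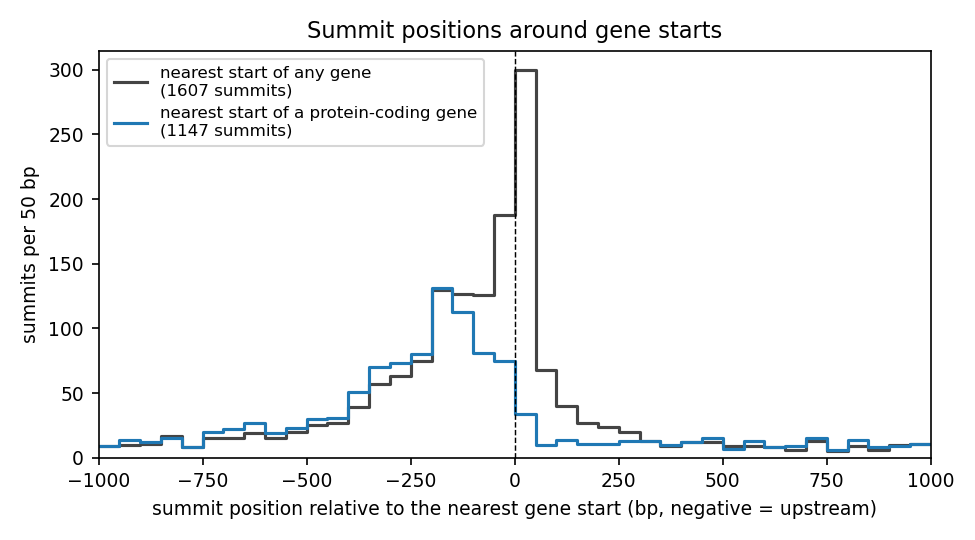
Number of nuclear summits per 50 bp (vertical) against their position relative to the nearest gene start in bp (horizontal, negative values upstream), for starts of any gene and for protein-coding starts alone. Around starts of any gene the highest bin is the 50 bp just inside the gene, with 300 summits, whereas around protein-coding starts it lies 150 to 200 bp upstream, with 131.

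Promoters and non-coding exons held more summits than shifted peaks did, and the bodies of genes held fewer. The 500 bp upstream of gene starts held 1025 summits (46.3% against 16.7%), and non-coding exons 238 (10.8% against 2.63%). The latter class also includes exons of pseudogenes and exon parts of protein-coding genes outside coding and UTR records. Coding exons held 111 (5.02% against 22.5%), introns 374 (16.9% against 31.7%), intergenic DNA 399 (18% against 22.3%) and 3' UTRs 23 (1.04% against 2.66%). Each of these 6 classes had a two-sided permutation p of 0.0020, the smallest that 1000 shifts can give, and an adjusted p of 0.0023 (Benjamini-Hochberg over 7 classes). Without peaks at tRNA, snoRNA or snRNA genes, a setting chosen after seeing the data, the intergenic share was 21.3% and no longer passed (permutation adjusted p = 0.44). In that setting the non-coding exon share was 5.03% and still passed (permutation adjusted p = 0.0028). The 5' UTR class, with 43 summits (1.94% against 1.54%), did not pass (permutation adjusted p = 0.17). It passed above chance with exons placed before promoters (2.71%, permutation adjusted p = 0.0040) and without small RNA peaks (2.25%, permutation adjusted p = 0.040). With the 500 strongest peaks it passed below chance (0.208%, permutation adjusted p = 0.0100), and without replicate 2 it was below chance and did not pass (1.39%, permutation adjusted p = 0.88).

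Summits lay between divergent genes more often than shifted summits did. Of the 1382 summits within 500 bp of a start, 397 (28.7%) lay between starts of a divergent pair no more than 2000 bp apart, against 13.5% for shifted summits that fell within 500 bp of a start (one-sided permutation p = 0.0001, the smallest possible). The peak at drr-2 is one example, with set-16, which encodes a histone methyltransferase, on the opposite strand. Positions between divergent starts are upstream of both, and the shifted summits were not matched for the upstream share. Part of the difference may therefore repeat the upstream position of summits, and a separate preference was not tested.

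Peak density on X against the autosomes depended on the denominator and on chromosome IV. The X chromosome carried 416 of the 2213 nuclear peaks (18.8%), against 12.8% of annotated gene starts, a density per start 1.57 times that of the autosomes (95% interval 1.41 to 1.75, exact binomial p = 2.5e-15, two-sided). Per 100 annotated gene starts, III had 10.4 peaks, I had 10.1, X 6.91, II 6.58, V 4.05 and IV, with 19704 starts of which 3281 are protein-coding, 1.57. Without IV the ratio of X to the autosomes was 0.983 (95% interval 0.880 to 1.10, exact binomial p = 0.78), so the difference per gene start rests on IV. Per protein-coding start the ratio was 1.46 (exact binomial p = 2.0e-11), and 1.43 without IV (exact binomial p = 4.3e-10); these 3 settings were chosen after seeing the data. X carries 276 of the 612 tRNA genes (45.1%), and without peaks at tRNA, snoRNA or snRNA genes the ratio was 1.31 (exact binomial p = 3.3e-05), a setting chosen after seeing the data. Per base of chromosome, a setting fixed at the start, the ratio was 1.08 and did not pass (exact binomial p = 0.16). By this last measure chromosome III had 29.0 peaks per Mb, I had 28.1, X 23.5, II 22.5, IV 17.7 and V 15.2.

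Autosome centres showed no difference that held for every denominator. The middle 33.3% of the autosomes held 595 of 1797 autosomal peaks (33.1%), and its density per annotated gene start was 1.25 times that of the arms (95% interval 1.13 to 1.38, exact binomial p = 8.4e-06, two-sided). Per protein-coding start, a setting chosen after seeing the data, the direction turned and the ratio was 0.804 (exact binomial p = 1.2e-05). Per base it was 0.990 (exact binomial p = 0.86). Without chromosome IV, also chosen after seeing the data, the ratio per annotated gene start turned to 0.836 (exact binomial p = 0.0010). The higher density in centres thus rests on the annotated starts of IV, 19704 in number, of which 3281 are protein-coding.

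Genes for tRNAs, snoRNAs and snRNAs were found at peaks far more often than by chance. A summit lay within 200 bp of 277 of 612 tRNA genes (45.3%, exact 95% interval 41.3 to 49.3%, against 1.04% for shifted peaks), 74 of 346 snoRNA genes (21.4%, 17.2 to 26.1%, against 1.21%) and 15 of 129 snRNA genes (11.6%, 6.66 to 18.5%, against 0.989%). Other ncRNA genes (536 of 7764, 6.90% against 1.17%) and miRNA genes (14 of 261, 5.36% against 1.10%) also exceeded the shifts, although the miRNA call was lost with the 500 strongest peaks (1.15%, permutation adjusted p = 0.15), and piRNA genes fell below them (18 of 15363, 0.117% against 0.737%). These 6 classes each had an adjusted p of 0.0030 in a two-sided permutation test (1000 shifts, Benjamini-Hochberg over 9 classes). Long intergenic RNA genes passed narrowly (13 of 194, 6.70% against 3.34%, permutation adjusted p = 0.041), and the call was lost without either replicate, with the other combined list (4.64%, permutation adjusted p = 0.63), with the summit inside the gene (permutation adjusted p = 0.57) and with the 500 strongest peaks (permutation adjusted p = 0.94). Antisense RNA genes (5 of 100, 5.00% against 2.65%, permutation adjusted p = 0.31) and rRNA genes (0 of 20, upper limit of the exact interval 16.8%) did not pass. Whether a peak could be called at rRNA genes was not tested.

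Peaks at tRNA genes made up 256 of the nuclear peaks (11.6%), with a median signal of 215 against 123 for other nuclear peaks. After C04A11.t1 and W03G11.t1, the strongest were at M02F4.t1 and M02F4.t2, which share a peak on X at 3035965 to 3036322 (signal 777). The strongest snoRNA peak, on V at 12303469 to 12303796, served both C51F7.3 and C51F7.4. Among snRNA genes the strongest peaks were at 2 loci on III that the annotation calls R07E5.16 (at 10989559 with signal 591 and at 4426911 with signal 352), followed by the spliced leader genes sls-2.4 (346) and sls-2.1 (339). The strongest miRNA genes were mir-51 (signal 652), mir-52 (447), mir-5549 (223) and mir-5595 (160). For the other classes, Y38F2AR.16, Y38F2AR.17, C56C10.14 and C56C10.15 led the ncRNA genes at the top peaks given above, 21ur-11631, 21ur-5229 (399), 21ur-13751 (367) and 21ur-2860 (181) the piRNA genes, and K09A9.12 (1020), linc-44 (250), linc-128 (183) and linc-117 (170) the long intergenic RNA genes. K09A9.12 shares its peak with ent-2.

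**Figure D4:**
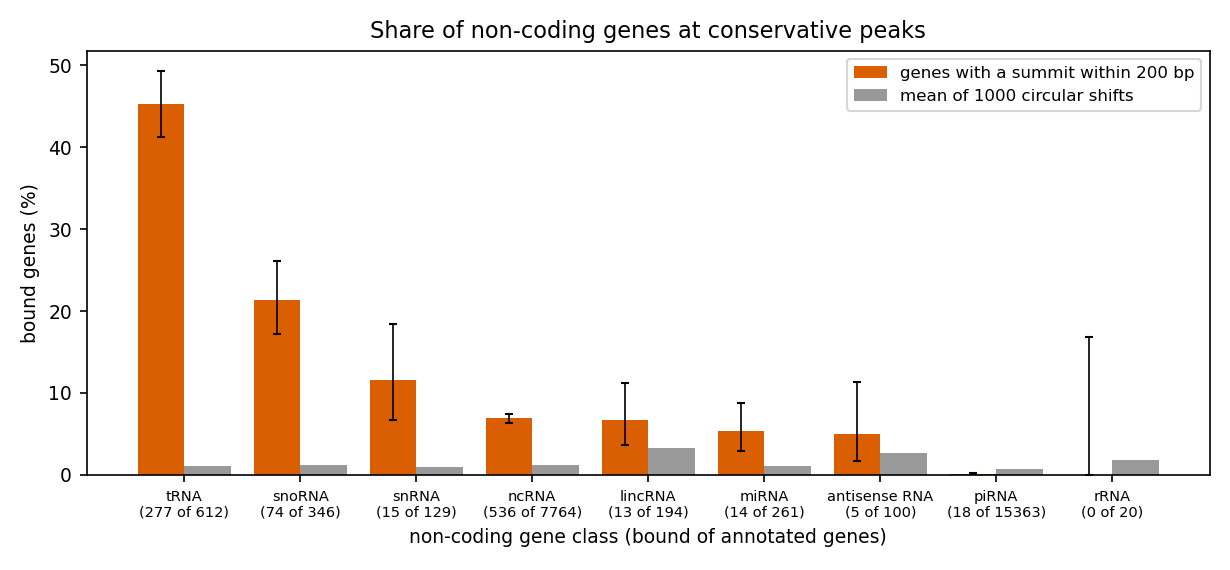
Share of annotated genes with a summit within 200 bp (orange, in percent, with exact 95% binomial intervals) and the mean of 1000 circular shifts (grey) for 9 classes of non-coding genes. The tRNA bar stands at 45.3% against 1.04%, the snoRNA bar at 21.4% against 1.21%, and the piRNA bar at 0.117% lies below its shifted value of 0.737%.

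Among protein-coding genes, those for the translation machinery, the mitochondrial respiratory chain, chaperones and chromatin proteins were bound more often than other genes. A gene was counted as bound when its start was the nearest to a summit and within 1000 bp, which gave 1527 genes, of which 833 were protein-coding (4.17% of 19973), 297 other ncRNA, 232 tRNA and 69 snoRNA. Ribosomal protein genes had 18 of 78 members bound (23.1%, against 4.10% of other protein-coding genes, odds ratio 7.02, Fisher's exact test adjusted p = 3.8e-08, Benjamini-Hochberg over 31 lists), led by rpl-3 (signal 900), rpl-15 (698), rps-28 (510) and rpl-35 (452). Translation factors had 9 of 40 bound (22.5%, odds ratio 6.73, exact adjusted p = 0.00025), with eef-1G, eif-3.C (413), iff-2 (366) and eif-3.B (262) in front. With every gene within 500 bp of a summit counted as bound, the share of ribosomal protein genes was 53.8%, of chaperones 35%, of respiratory chain genes 32.5% and of translation factors 30%. The count for ribosomal proteins was 27 when each peak was given to its nearest protein-coding start, a setting chosen after seeing the data.

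Heat shock and chaperone genes had 11 of 60 bound (18.3%, odds ratio 5.21, exact adjusted p = 0.00025), with the strongest peaks at the J-domain co-chaperone genes dnj-28 (390), dnj-29 (383), dnj-9 (210) and dnj-5 (208). Their share was 10% without replicate 1 (exact adjusted p = 0.016) and 10% without replicate 2 (exact adjusted p = 0.0069). Respiratory chain and ATP synthase genes had 8 of 40 bound (20%, odds ratio 5.79, exact adjusted p = 0.0013), led by the cytochrome oxidase genes cox-5B (310) and cox-5A (266), cyc-1 (244) and nuo-2 (223). This share was 17.5% without replicate 1 (exact adjusted p = 0.00038) and 10% without replicate 2, close to the threshold (exact adjusted p = 0.040). Chromatin regulators had 7 of 38 bound (18.4%, odds ratio 5.22, exact adjusted p = 0.0045), led by the histone methyltransferase gene set-25 (262), lin-9 (181), set-2 (141) and bet-2 (133). This last call was lost without replicate 2, with 7.89% bound (exact adjusted p = 0.14), and with the 500 strongest peaks, with 2.63% bound (exact adjusted p = 0.999).

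Receptor families were bound less often than other genes. Chemoreceptor genes, which act in sensory neurons, had 7 of 1308 bound (0.535% against 4.43%, odds ratio 0.116, Fisher's exact adjusted p = 3.5e-15), with sri-5 (signal 271), srh-16 (236), srbc-38 (161) and srz-82 (105) the strongest. Nuclear hormone receptor genes had 3 of 269 bound (1.12% against 4.21%, odds ratio 0.256, exact adjusted p = 0.035), namely nhr-141 (206), nhr-47 (173) and nhr-1 (118.9). The nuclear hormone receptor call was lost with chance taken from circular shifts (permutation adjusted p = 0.32), with the 500 strongest peaks and without either replicate. The shift setting compares with shifted positions (2.81%), a lower baseline than the 4.21% of other genes.

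The other 24 lists did not pass. Splicing factors came closest, with 5 of 35 bound (Fisher's exact adjusted p = 0.056, strongest rsp-1 at signal 155). With chance from circular shifts they passed (permutation adjusted p = 0.0088), as did histones (6 of 72, permutation adjusted p = 0.015, strongest his-37 at 239). Shifted summits lie at gene starts less often, so their baselines (2.85% and 1.58%) were below the shares of other genes (4.15% and 4.16%). Passing against shifts therefore does not show that either list exceeds other genes. Splicing factors also passed with every gene within 500 bp (22.9%, exact adjusted p = 0.0015), the nearest start within 2000 bp (20%, exact adjusted p = 0.0059) and, chosen after seeing the data, the nearest protein-coding start (17.1%, exact adjusted p = 0.039). Histones also passed without replicate 1 (11.1%, exact adjusted p = 0.0024) and with every gene within 500 bp (16.7%, exact adjusted p = 0.0015), and tubulins and actins with the nearest protein-coding start (22.2%, exact adjusted p = 0.048). Among lists of general cell function were aminoacyl-tRNA synthetases (4 of 32, strongest ears-2 at 744), proteasome subunits (3 of 33, rpn-2 at 180), vacuolar ATPase (2 of 20, vha-1 at 130), tubulins and actins (2 of 18, tba-2 at 200), cell cycle and replication genes (4 of 39, lin-35 at 333), dosage compensation and condensin genes (2 of 16, hcp-6 at 212), small RNA pathway genes (1 of 27, alg-1 at 132) and germline and P granule genes (1 of 32, cgh-1 at 149). Tissue and signalling lists included body wall muscle (3 of 21, unc-112 at 155), epidermis (1 of 19, elt-6 at 114), pan-neuronal genes (2 of 20, ehs-1 at 124), Wnt pathway (2 of 24, mig-5 at 137), Notch pathway (1 of 20, adm-4 at 99.1), collagens (9 of 177, col-52 at 182) and ceh homeobox genes (2 of 63, ceh-20 at 134). No member was bound among 6 Hox genes, 17 endoderm and intestine regulators, 12 pharynx genes, 30 neuronal fate regulators, 25 ztf zinc finger genes, 25 bHLH genes or 44 major sperm protein genes; the exact 95% interval of these shares reached from 8.04% for the last list to 45.9% for the Hox genes.

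**Figure D5:**
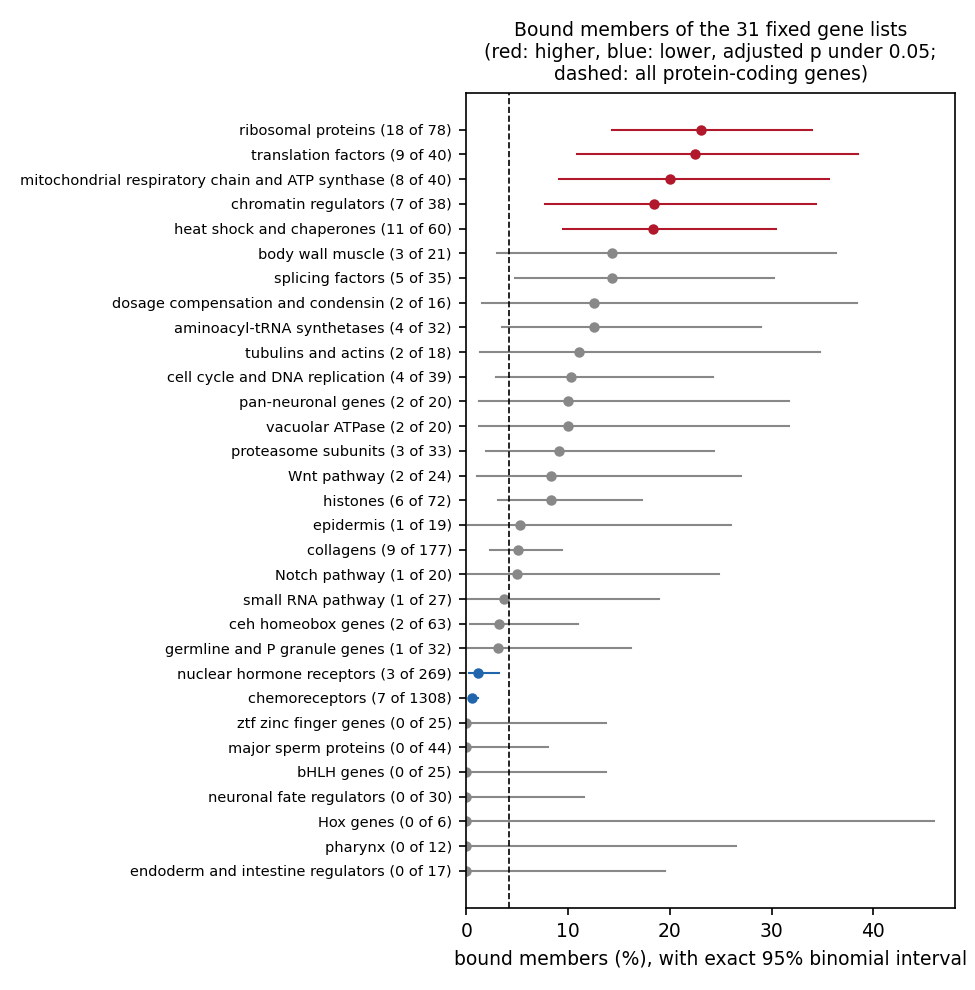
Percent of members bound (points, with exact 95% binomial intervals) for the 31 fixed gene lists, with the dashed line at the share of all protein-coding genes, 4.17%. The 5 lists in red, from ribosomal proteins at 23.1% to heat shock and chaperones at 18.3%, passed above it, and the 2 in blue, nuclear hormone receptors at 1.12% and chemoreceptors at 0.535%, passed below it.

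Many short words were enriched under summits, and 1 of the leading words lay mostly at tRNA genes. In windows reaching 50 bp to either side of 1168 summits on I, II and III, 566 of 9999 tested 8-mers were more frequent than in windows 300 bp to either side (exact binomial test, Benjamini-Hochberg adjusted p under the threshold of 0.05). The 5 leading words were AAGTGCGC (3.17% of summits against 0.171% of flanks), GCAAACAC (3.77% against 0.385%), AAACGCGC (3.17% against 0.214%), CTTGCGCA (2.57% against 0.0856%) and AGTGGTTA (2.48% against 0.0856%). They were chosen so that none shared 6 bases in a row with another, and words that overlapped them in this way were left out. All 5 were also enriched at the 1045 summits on IV, V and X, which took no part in choosing them, with one-sided exact binomial p from 7.0e-21 for AGTGGTTA (4.59% against 0.0957%) to 0.00029 for CTTGCGCA (1.15% against 0.144%). In a comparison chosen after seeing the data, AGTGGTTA lay in 52 of 256 peaks at tRNA genes (20.3%) and in 25 of 1957 other nuclear peaks (1.28%, Fisher's exact p = 1.4e-32), and the other 4 words were less frequent at tRNA genes than elsewhere. Genes for tRNAs lie on every nuclear chromosome, and 387 of the 612 belong to sets of more than 5 identical copies. The held-out summits are therefore not an independent test of AGTGGTTA. Each word marked under 5% of summits. Summit and flank windows were not matched for base composition, so its part in these counts was not tested.

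The tagged gene itself carried no peak. No region of any of the 4 thresholded lists lay within 1000 bp of ztf-23 (I: 3052048 to 3059165, minus strand), and the nearest nuclear peak of the conservative list (I: 3037838 to 3038181, signal 141) was 13866 bp away. Of the 4 longer ranked lists, that of replicate 1 alone held regions there, at I: 3059407 to 3059730 (signal 37.3, score 42) and I: 3054040 to 3054363 (signal 28.6, score 33), well under the score of 830 at which the conservative list begins.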

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

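The tests on mitochondrial bins, on ribosomal protein genes and on the shared sequence at small RNA genes were chosen only after the result was seen; the snoRNA test was added once the tRNA result was known. No biological explanation was tested, since the design has 1 group and no control library was analysed here.

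The conservative list held 21 peaks on the mitochondrial chromosome, data outside the nuclear measures of the report. Their signals reached 2616 with a median of 1101, against 128 for nuclear peaks, and their density was 1522 per Mb against 22.1. Replicate 1 alone had 21 such peaks and replicate 2 had 23. The many copies of the mitochondrial genome per cell are a candidate explanation: summits would then spread over the chromosome, and 14 of its 14 bins of 1000 bp (100%) held one, although the positions had been seen when this test was chosen. Peaks covered 42.2% of its bases, and specific binding there stays open without a control.

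The combined ranked list held 2408 regions at or above a score of 830, the conservative list's lowest. Of these, 174 were absent from the conservative list of 2234 peaks, and the report's comparisons do not use them. They had a median signal of 257 and reached 4930. They fell into 72 clusters, of which the fullest were on I at 4535913 to 4547306 (11 regions, over Y119C1B.13 and zig-9) and at 10945999 to 10953000 (11 regions, at Y95D11A.5). The median share of their 30-base words found elsewhere in the genome was 93.0%, against 0% around nuclear conservative summits. Their scores do not account for their absence. The thresholded lists were made with a further input file that the ranked lists lack. Removal of repeated sequence with that file is therefore a candidate reason for the absence of these regions. What the file holds was not stated, so this was not tested.

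Peaks at tRNA and snoRNA genes were far above chance. The snoRNA genes with no repeated 30-base word were bound in 22.6% of cases (67 of 297, exact 95% interval 17.9 to 27.7%, against 1.21% by chance), which argues against reads shared between gene copies there. For tRNA genes that explanation stays open: 0 of 20 genes (0%, upper limit 16.8%) without a repeated word were bound, against 46.8% of 592 with one, and whether those 20 are transcribed was not tested. The 143 tRNA genes whose full sequence occurs once were bound in 28.7% of cases (exact 95% interval 21.4 to 36.8%, against 1.04% by chance), against 47.6% for 2 to 5 identical copies and 50.9% for more than 5; the share above chance without an identical copy and its rise with copies leave shared reads open, in part or in whole, since shorter stretches are shared too. Capture of strongly transcribed genes of any kind also stays open, since ribosomal protein genes were bound in 23.1% of cases (exact 95% interval 14.3 to 34.0%) against 4.10% of other protein-coding genes. The sequence shared by the strongest peaks lay under 0 of the 330 peaks at tRNA or snoRNA genes, which argues against this sequence as their source. The comparison with other peaks (Fisher's exact p = 0.23) decides nothing, as the sequence has only 32 places in the genome.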

How the results depend on the processing

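No paired analysis was possible because there is 1 group. Among the alternative values of the main results, 100 kept their direction and their side of the threshold, or stayed within 1.5 times for counts; these include a score of at least 830, which removed no peak. The own lists, called on 1 replicate's reads, and the 500 strongest peaks are smaller by construction. Leaving out a replicate gave 959 to 1233 peaks, 755 to 940 bound genes and 199 to 285 enriched words; the 500 strongest peaks gave 440 bound genes and 72 words, and 51 bp windows 182 words. The X to autosome ratio per base was 1.08, no longer past the threshold, and without chromosome IV it reversed to 0.983. The centre to arm ratio reversed to 0.990 per base, to 0.804 per protein-coding start and to 0.836 without IV. The protein-coding and IV settings were chosen after seeing the data; both ratios per gene start rest on IV, with 19704 starts and 1.57 peaks per 100 starts. The correlation between replicates moved to 0.712 (Pearson on log2), 0.869 (summits within 100 bp) and 0.670 (ranked lists); the cause was not tested. Replicate 1's ranked list held 2 regions at ztf-23 against 0 in the main list. The 5' UTR share passed below chance for the 500 strongest peaks (0.208%), fell below it without passing without replicate 2 (1.39%, against 1.90% without replicate 1), and passed above it with exons before promoters (2.71%) and without small RNA peaks (2.25%, chosen after seeing the data); the cause was not tested. The 500 strongest peaks also ended the calls of chromatin regulators (2.63% bound), miRNA genes (1.15%) and long intergenic RNA genes (1.03%). Lists below other genes went from 2 to 1 with the 500 strongest peaks, either own list or chance from shifts, which compares with shifted positions rather than other genes. Unknown depth limits the weak peaks.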

Other observations

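The tests on tRNA groups, and those on the shared sequence except that on repeated words, were chosen only after the result was seen.

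Some other RNA genes, picked after their values were seen and not tested against chance, also lay at peaks. The RNase P RNA gene rpr-1 (signal 576) and the RNase MRP RNA gene mrpr-1 (449), each present once, had a summit within 200 bp, and so had 4 of 5 signal recognition particle RNA genes, from srpr-2.2 (475) to srpr-2.1 (203), while 0 of 20 rRNA genes were at peaks (upper limit 16.8%). Of the spliced leader genes 5 of 18 sls-2 genes were at peaks, led by sls-2.4 (346), and 0 of 12 sls-1 genes (upper limit 26.5%). Whether a peak could be called at the rRNA and sls-1 genes was not tested. High-scoring regions of repeated sequence were missing from the conservative list, so these counts do not show that the genes are unbound. Over 607 tRNA genes with an annotated amino acid, the bound share ran from 25% for histidine (5 of 20) to 59.3% for aspartate (16 of 27), leaving aside the single selenocysteine gene (0 of 1), and no difference between amino acids passed the threshold (permutation p = 0.19, 100000 permutations). On X 43.1% of 276 tRNA genes were bound, and on the autosomes 47.0% of 336 (Fisher's exact p = 0.37), where the share ran from 29.5% on V (exact 95% interval 19.7 to 40.9%) to 57.8% on III.

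The strongest peaks shared a sequence: GGGGC, C after any base, 1 or 2 further bases, then ACGCA, read from either strand. This form was picked from several once the strongest peaks and the counts of each form had been seen. It occurred at 32 places in the nuclear genome, of which 17 lay within 150 bp of a conservative summit, under 12 peaks. Those were 7 of the 9 strongest (all but trap-3 and tasp-1), 4 of the 91 ranked 10 to 100 and 1 of the 2113 below, and 0 peaks held it 1000 bp away. That 0 says little, since a sequence with 32 places would rarely fall there by chance. Examples are GGGGCACATACGCA at eef-1G (V: 10965712 to 10965725) and near eef-1A.2 (X: 7823345 to 7823358), GGGGCACACACGCA near dkc-1 (III: 10748204 to 10748217) and GGGGCGCTACGCA near wip-1 (III: 5018229 to 5018241).

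A hypothesis is that the tagged protein, or a partner, binds this sequence directly. Against reads shared between repeats as the source, the median share of repeated 30-base words around the 12 summits was 0%, although 4 of them (ranks 10, 11, 25 and 397) had 21.7 to 59.9%. A first test for chance compared ranks 10 to 100 with lower ranks (Fisher's exact p = 1.3e-05); it was set aside after its result was seen, because 3 of the 4 peaks at ranks 10 to 100 (ranks 10, 11 and 25, not 20) lie in partly repeated sequence. In its replacement, whose reading was also settled after its result, chance match to a pattern written from the same peaks cannot be told apart from binding: outside the 9 strongest peaks, 1 of 12 loci without repeated words lay under a summit, against 0.654% of random positions (one-sided exact binomial p = 0.076), and with the 8 loci that have such words 5 of 20 did (exact binomial p = 1.7e-07). The bases of the pattern in reversed order occurred at 12 places with 0 under a peak, which does not address the fitting of the pattern to the strongest peaks. With 12 places and 0.654% of random positions under a summit, 0 was likely for any sequence. Of the 32 places of the pattern, 15 lay under no peak, so the sequence alone may not be enough.

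Of the nuclear conservative peaks, 105 had a signal below 50 despite a median score of 1000, and all but 1 of them overlapped a stronger peak of the same list.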
